A study of Homo sapiens with 58 samples.

How the data were processed

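RNA, ChIP-seq and CUT&RUN libraries of human umbilical artery (HUAEC) and vein (HUVEC) endothelial cells were grouped from the sample labels. Of 58 samples, 26 had values that were used, in 12 RNA libraries and 14 peak lists. The other 32, which include inputs, HUAEC ERG, H3K27me3 and H3K27ac after knockdown, were not analysed here. Per the labels' protocols, HUAEC and HUVEC were isolated from the same cords with collagenase and used before passage 3 (the passage entry of each sample is 3), RNA was polyA-selected, and for knockdown HUVEC were transduced with lentivirus carrying a control hairpin or a hairpin against NR2F2. Which libraries share a cord was not given in the sources used here. Replicates are named by the number in the sample titles, where HUAEC RNA has replicates 1, 2 and 4.

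The submitters' processing notes name TopHat2 and edgeR for RNA, Bowtie2 and MACS2 for the libraries, and the build hg19, without versions. The counting tool, the annotation, the strand setting and the peak thresholds are not given in the sources used here. The authors deposited 1 RNA table per comparison, each with values of 6 libraries, which are a scaled signal per gene and not raw counts. Every value was a whole number times a step per library of 0.9873 to 0.9984 (100% whole at a tolerance of 1e-06). In 8 of 12 libraries the frequencies of the whole numbers of 50 to 500 were periodic (periodogram power above the highest of 1000 simulated draws without scaling), a pattern that earlier scaling and rounding can leave, and in the other 4 this was not seen. Whether the whole numbers are reads was therefore left open, and they were not taken as reads. The lowest mean of a gene over the libraries was 62.9 in the HUAEC and HUVEC table and 30.1 in the knockdown table, so low genes are absent from both. The same tables hold the authors' deposited comparison, with a log2 fold change, a fold (ratio), p-values, adjusted p-values and the −log10 of the adjusted p-value per gene, per the file headers. These values were set beside the own tests only as counts. The names of both deposited RNA tables refer to DESeq2, which the processing notes do not name. The peak files hold 1 list per library. Per the file headers and values, the authors deposited a score per peak for all targets, and for ERG and HDAC1 also a fold enrichment (ratio) and −log10 p and q values. Scores were used only to rank peaks within a list. Tables were normalized separately, so tests were made only within a table.

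Because the table values are not whole-number counts, the planned count test was replaced by limma on log2(value + 1), the test named in advance for normalized values. Fold changes are on this scale, which understates changes of low genes. Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 2 groups of 3 libraries each and no covariate. P-values were adjusted by Benjamini-Hochberg over all genes of a table, 10924 for HUVEC minus HUAEC and 12589 for knockdown minus control, with a threshold of 0.05. A change of at least 1.5-fold was tested with treat. The 19 gene lists covered arterial, venous, lymphatic and pan-endothelial markers, markers of smooth muscle, fibroblasts, blood cells and epithelium, and pathways. Lists with at least 3 measured members, 18 in each table, were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. The blood cell list had 1 measured member, CD68 (log2 0.06 between HUVEC and HUAEC and 0.69 after knockdown), and was not tested.

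The groups, tests, gene lists, alternatives and the rule for named genes were set before the data were examined, except where a later choice is named. Named genes were NR2F2, the arterial and venous markers, and the 10 highest and 10 lowest log2 changes among genes past the threshold whose groups did not overlap and whose mean log2 CPM, computed here from the deposited values, was at least 1. Up to 4 members with the smallest adjusted p stand for each other list that passed. Further members were named after their values were seen. Some genes that these rules name are not reported here. XIST and related genes, Y-linked genes and chromosome Y were left out everywhere.

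Peaks on numbered chromosomes and X were merged across the libraries of a target where they overlapped by at least 1 bp (bedtools 2.31.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6). A region counted as shared with a peak of all 4 libraries, and as restricted to a cell type with a peak of both its libraries and of neither other library. An EP300 region counted as having a factor if it overlapped a peak of each of the factor's libraries. Those peaks need not overlap each other, so wide regions can meet this rule more easily. H3K27ac at EP300 regions was counted by the same kind of overlap. Only the peak regions of a factor counted by themselves were merged peaks with both libraries in them. Overlaps were tested over regions with two-sided Fisher's exact tests (scipy 1.17.1) with 95% intervals of the odds ratio by Woolf's method, and the interval for genes called in both RNA comparisons is the conditional one of Fisher's test in R. The family held 10 such tests, of which the 4 within shared or HUVEC-only regions alone were added after the data were seen. With 2 libraries per group no test across libraries was made. Intervals cover counting error over regions only. Links from regions to genes and a filter on distance from transcription start sites need an annotation of hg19 and were not run. Coordinates are 1-based.

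Before use, the procedures were tested on simulated data. With 200 changed genes planted among those of the HUAEC and HUVEC table, 31.3% of 1.5-fold, 56.7% of 2-fold and 87.9% of 4-fold changes were called, and 4.1% of the calls were false. For the knockdown table the values were 80.6%, 95.5% and 100%, with 3.66% false. Planted region counts were recovered exactly, and 9 of 200 unlinked draws had p under 0.05. The simulations used independent noise per gene, intervals placed apart and independent counts. They therefore do not measure errors that arise from correlated genes or clustered regions. Alternatives were another pseudocount (0.1), a filter at a CPM of 1 in 3 libraries, a stricter threshold of 0.01, replicate blocks, leaving out each library, fry in place of camera, and for peaks a stricter score, lists of equal length, an overlap of at least 0.5 of the shorter interval, and peaks of either library. Quantile normalization, scaling to equal totals, strata of region width and score rank, the alternatives of those 4 tests and those of the ratios of odds ratios were added after the data were seen. Score ranks were taken within the EP300 lists of 1 cell type. Figures were drawn with matplotlib 3.10.9.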

Results

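Human umbilical vein endothelial cells (HUVEC) and human umbilical artery endothelial cells (HUAEC) were compared to describe enhancers and genes that differ between artery and vein. Both are primary cells taken from umbilical cords, used at low passage. The data analysed here came from 26 libraries. Polyadenylated RNA was sequenced from 3 HUAEC and 3 HUVEC libraries, and from HUVEC that carried a control short hairpin RNA (3 libraries) or a hairpin against NR2F2 (3 libraries). NR2F2, also called COUP-TFII, is a nuclear receptor known for its part in venous identity. Chromatin was mapped in 2 libraries per target: the active enhancer and promoter mark H3K27ac and the coactivator EP300 in both cell types, and the transcription factors NR2F2 and ERG and the deacetylase HDAC1 in HUVEC. ChIP-seq was used for all targets except HDAC1, which was mapped by CUT&RUN, a method that cuts chromatin at the bound protein in place of shearing it. The authors' normalized RNA values summed to 24668220 to 26907417 per HUAEC or HUVEC library and to 51693501 to 54639919 per hairpin library. These sums are of scaled values and are not read depths. The read depths of the peak libraries were not used here.

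Arterial and venous marker genes separated HUAEC from HUVEC RNA. NR2F2 stood at 11095 ± 735 normalized units in HUVEC (SD, n = 3) and at 399 ± 256 in HUAEC (SD, n = 3), a log2 difference of 5.11 (SE 0.53, adjusted p = 0.00095). Other venous genes were higher in HUVEC, among them EMCN, a sialomucin of venous and capillary endothelium (log2 2.81, SE 0.15), the adhesion molecule SELP (2.30, SE 0.41), the semaphorin and VEGF-C co-receptor NRP2 (2.23, SE 0.30) and EPHB4, the receptor for ephrin-B2 (1.65, SE 0.18). HUAEC had more RNA of the Notch target HEY2, with 2114, 1224 and 1916 units against 0, 1 and 0 in HUVEC, and of the Notch ligand DLL4 (log2 -2.86, SE 0.34), the receptor NOTCH4 (8.02-fold, SE 0.23 on the log2 scale) and the arterial ligand EFNB2 (-1.59, SE 0.22). The gap junction gene GJA5 stood at 3014 ± 2072 units in HUAEC and 135 ± 181 in HUVEC (SD, n = 3 each; log2 -5.24, SE 0.91).

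Of 23 arterial markers measured, 11 were higher in HUAEC, 2 were higher in HUVEC and 10 did not pass the threshold of adjusted p 0.05. Adjusted over the list alone, the counts were 15 and 4. The other members that were higher in HUAEC were UNC5B (log2 -4.54), DKK2 (-4.58), HEY1 (-3.01), SEMA3G (-2.61), SOX17 (-1.46) and BMX (-0.65). The Notch ligand JAG2 (log2 1.26) and the elastic fibre protein FBLN5 (2.21) were higher in HUVEC. NOTCH1 (log2 0.01, adjusted p = 0.958) and NRP1 (-0.07, adjusted p = 0.884) did not pass, nor did CXCR4 (-2.12, adjusted p = 0.0536) and IGFBP3 (-2.92, adjusted p = 0.0914). CXCR4 passed without HUAEC replicate 2 (-2.79, adjusted p = 0.00677), as did ALDH1A1 (0.82, adjusted p = 0.0451), and IGFBP3 passed without HUAEC replicate 4 (-4.10, adjusted p = 0.00324). BMX did not pass without HUAEC replicate 2 (adjusted p = 0.0598) or without HUVEC replicate 3 (adjusted p = 0.0815). Of 9 venous markers, 6 were higher in HUVEC and none in HUAEC, and adjusted over the list alone the counts were 6 and 1. FLT4 (2.82-fold) was the last of the 6, and PLVAP (0.45), VCAM1 (0.07) and GPR126 (-0.66) did not pass, though GPR126 did without HUVEC replicate 2 (-0.86, adjusted p = 0.0433). Both lists passed the list test (camera, adjusted p = 2.64e-06 for arterial and 9.03e-06 for venous markers), but not with a correlation between genes estimated from the data (adjusted p = 0.229 with an estimated correlation for each).

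**Figure D1:**
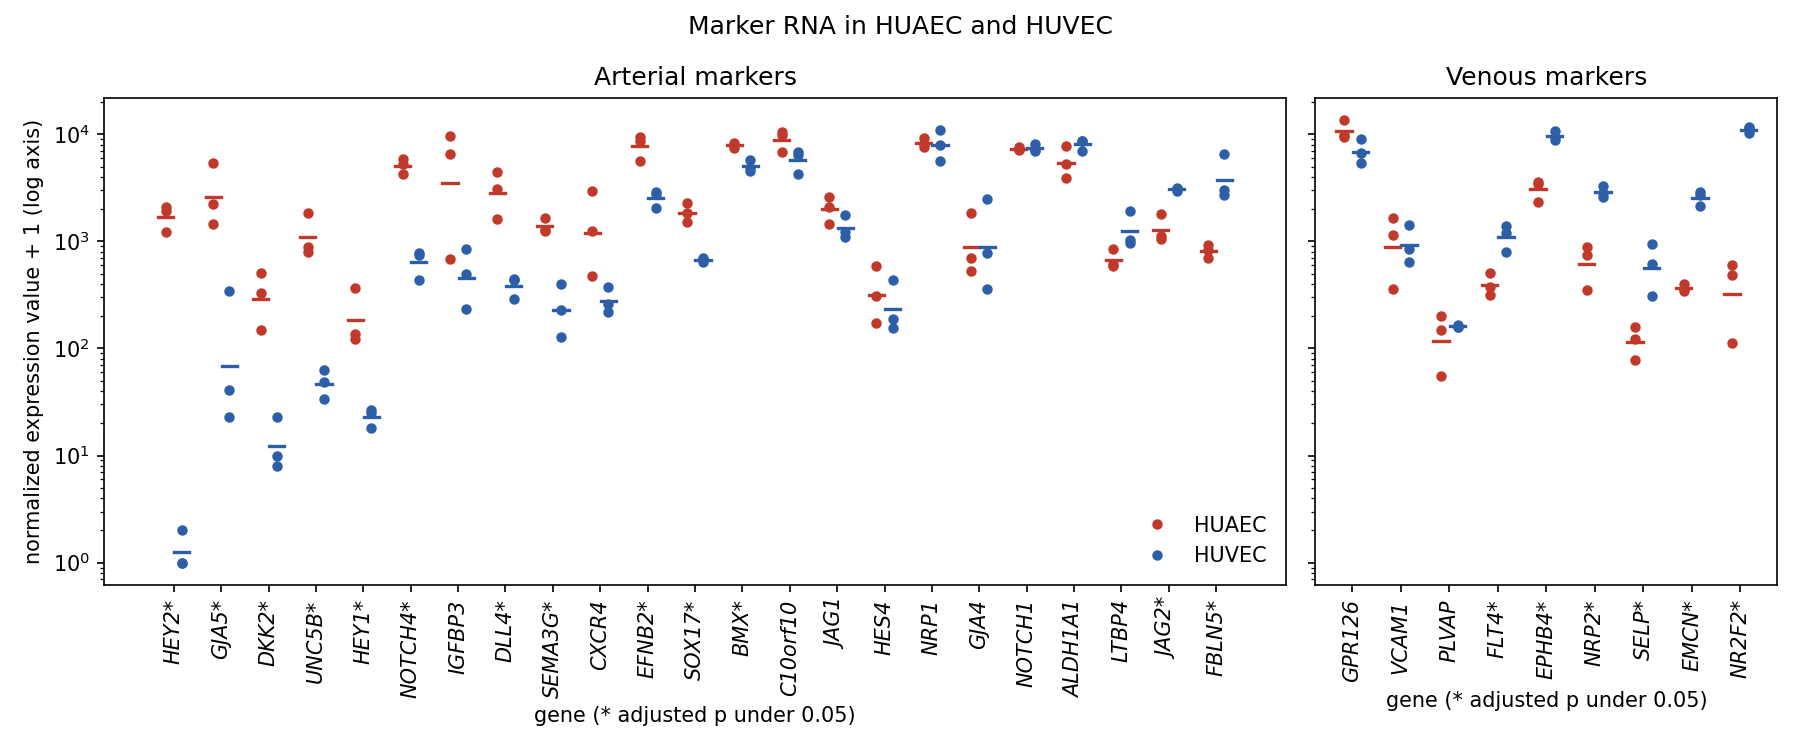
Normalized RNA value plus 1 (log axis) of every measured arterial (left) and venous (right) marker in 3 HUAEC libraries (red) and 3 HUVEC libraries (blue), with points for libraries, short lines for geometric means and asterisks for genes past adjusted p 0.05. HEY2 lay at 1224 to 2114 units in HUAEC and at 0 to 1 in HUVEC, and NR2F2 at 112 to 600 in HUAEC and 10254 to 11614 in HUVEC.

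Across 10924 genes, 375 were higher in HUVEC and 525 were higher in HUAEC at adjusted p 0.05, 203 and 324 of them by at least 2-fold. The authors' deposited table called 1403 genes at the same threshold, and 896 of the 900 genes called here were among them with the same direction. Beside NR2F2, genes with a large excess in HUVEC included PTGS1, which encodes cyclooxygenase 1 (log2 8.82), the BMP family ligand GDF6 (6.27), the semaphorin receptor PLXNA4 (5.26), FAM174B (5.23), the atypical protein kinase PRKCZ (4.62), LYPD1 (4.58) and the imprinted gene NNAT (4.52). PTGS1 stood at 6462 ± 4561 units in HUVEC and at 14.6 ± 10.1 in HUAEC (SD, n = 3 each). Among genes with a mean log2 CPM of at least 1, the 10 with the greatest excess in HUAEC were the collagen genes COL6A3 (log2 -9.07) and COL1A1 (-8.45), XG (-8.30), the proteoglycan genes ACAN (-8.05), CSPG4 (-7.16) and VCAN (-6.09), the laminin gene LAMA2 (-6.97), the imprinted noncoding RNA H19 (-6.79), CYTL1 (-6.40) and the transcription factor TFAP2A (-6.28). HEY2 (-10.40) and other genes below that mean are not in this ranking. Without HUVEC replicate 3 the counts were 186 and 272, and without HUAEC replicate 2 the count higher in HUAEC was 327. A replicate block gave 168 and 262 by title number and 511 and 822 by library name number.

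Some markers of fibroblasts and of smooth muscle were higher in the artery group. Of 5 fibroblast markers measured, COL1A1, COL1A2 (log2 -3.76) and FBLN1 (-1.64) were higher in HUAEC, while COL3A1 (-0.71) and POSTN (-2.11) did not pass (camera, adjusted p = 0.000366; adjusted p = 0.311 with an estimated correlation). Of 6 smooth muscle and pericyte markers, CSPG4, the smooth muscle actin ACTG2 (-6.71) and NOTCH3 (-1.55) were higher in HUAEC, while ACTA2 (-2.01), TAGLN (0.11) and RGS5 (2.73) did not pass (camera, adjusted p = 0.0161; adjusted p = 0.567 with an estimated correlation). HUAEC replicate 4 had the lowest value of the 3 HUAEC libraries for COL1A1 (19107 units against 102692 and 83419), COL6A3 (3870 against 18045 and 18032), CSPG4 (590.5 against 2105 and 1903), ACTG2 (24 against 779 and 467) and ACTA2 (424 against 3386 and 1580), and all 3 libraries were alike for FBLN1 (609, 596 and 570). COL1A1 reached 42.5, 481 and 181 units in HUVEC. HUVEC replicate 1 was the highest HUVEC library for COL3A1 (9457 units against 2432 and 2443) and COL1A2 (2974 against 685 and 319). It was also highest for TAGLN (5529 against 1111 and 976), above every HUAEC library (4885, 2670 and 362.5). For COL1A1 and RGS5 it was the lowest HUVEC library. For the arterial genes HEY2, DLL4 and GJA5, replicate 4 lay between the other HUAEC libraries, at 1916, 3060 and 2230 units, and for NOTCH4 it was the lowest, at 4280. Adjusted over the list alone, 3 fibroblast markers were higher in HUAEC and none in HUVEC, and 4 and 1 smooth muscle markers.

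Among the other gene lists, 4 passed the list test between HUAEC and HUVEC, and none of these held with an estimated correlation. The Notch pathway list leaned to HUAEC (adjusted p = 0.02; adjusted p = 0.394 with an estimated correlation), with 5 of 25 genes higher there (HEY2, HEY1, NOTCH3, NOTCH4 and DLL4) and NOTCH2 (log2 0.58) and JAG2 higher in HUVEC (6 and 2 adjusted over the list alone). The median log2 difference of the Notch list was -0.134. HEY2, HEY1, NOTCH4, DLL4 and JAG2 were also counted among the arterial markers, so the 2 lists are not separate results. NOTCH3 was also counted among the smooth muscle and pericyte markers, and was lowest in HUAEC replicate 4 (647 units against 1580 and 1361). BMP and TGF-beta signalling leaned to HUVEC (adjusted p = 0.00424; adjusted p = 0.311 with an estimated correlation). In it 7 of 22 genes were higher in HUVEC, among them the TGF-beta binding protein LTBP1 (1.85), the ligands TGFB2 (1.92) and BMP2 (0.95) and the co-receptor ENG (1.04), and the receptors TGFBR2 (-1.08) and TGFBR3 (-1.20) were higher in HUAEC (10 and 3 adjusted over the list alone). Interferon response genes leaned to HUAEC (adjusted p = 1.59e-06; adjusted p = 0.567 with an estimated correlation), with MX2 (-5.03), IFIT3 (-1.99) and IFIH1 (-1.60) past the threshold of 20 measured, and 11 adjusted over the list alone. This list varied within groups as well: IFI6 stood at 4952, 4579 and 21418 units in HUAEC and at 13886, 618 and 465 in HUVEC. Cell cycle genes leaned to HUVEC (adjusted p = 0.000915; adjusted p = 0.66 with an estimated correlation) by small amounts, with CCNE1 (0.84) and TYMS (0.56) the only members of 36 past the threshold, and none adjusted over the list alone.

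The remaining 10 lists tested did not pass between the cell types. Adjusted over the list alone, genes higher in HUVEC and in HUAEC numbered 1 and 3 for pan-endothelial markers, 5 and 8 for axon guidance, 5 and 3 for HOX, 2 and 2 for chemokine, 1 and 2 for hypoxia and 1 and 1 for epithelial genes, and the counts of the shear-responsive, inflammatory and lymphatic lists stayed at those given here. Pan-endothelial markers (adjusted p = 0.103) had 14 of 18 genes below the threshold, including CDH5 (log2 0.28) and PECAM1 (-0.21), while CLDN5 (-1.59), FLT1 (-1.30) and KDR (-1.15) were higher in HUAEC and ENG in HUVEC. Of 21 axon guidance and Eph-ephrin genes (adjusted p = 0.286), 7 were higher in HUAEC and 2 in HUVEC. HOX genes (adjusted p = 0.365) had HOXA4 (2.25), HOXA5 (0.89) and HOXD8 (0.87) higher in HUVEC out of 16. In the chemokine list (adjusted p = 0.819) ACKR3 (1.63) was higher in HUVEC and its ligand CXCL12 (-3.76) in HUAEC. Of the shear-responsive genes (adjusted p = 0.219) NQO1 (-1.52) passed, of the inflammatory genes (0.366) CXCL2 (-1.45) and of the hypoxia and glycolysis genes (0.845) SLC2A3 (-2.45), each higher in HUAEC. The cholesterol genes did not pass as a list (adjusted p = 0.749). FLT4 was the only lymphatic marker past the threshold (adjusted p of the list 0.132), and no epithelial marker passed over all genes (0.845).

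The hairpin against NR2F2 lowered NR2F2 RNA from 19855, 18903 and 19627 units in the 3 control libraries to 8682, 8222 and 8889 (log2 -1.18, SE 0.04, adjusted p = 3.88e-11), a level 2.26-fold lower than in the control. Genes of cell division fell together. All 36 cell cycle genes fell by at least 2-fold, with a median log2 change of -4.71 (camera, adjusted p = 9.06e-18; adjusted p = 0.0118 with an estimated correlation). The ribonucleotide reductase subunit RRM2 went from 17325 ± 302 to 507 ± 22.3 units (SD, n = 3 each), the topoisomerase TOP2A changed by -5.62 on the log2 scale, the cyclin CCNA2 by -4.55 and the mitotic activator CDC20 by -5.31. Among genes with a mean log2 CPM of at least 1, the 10 with the lowest log2 change were FAM111B (-7.07), MCM10 (-6.66), DEPDC1 (-6.10), NEK2 (-6.00), CLSPN (-5.95), CENPA (-5.92), ASPM (-5.86), SGOL1 (-5.81), SKA3 (-5.73) and UBE2C (-5.70).

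Arterial markers divided in direction after knockdown. Of 21 measured, 12 rose, 8 fell and 1 did not pass, and adjusted over the list alone the counts were 12 and 8 (camera, adjusted p = 0.707). GJA5 was listed at 0, 0 and 9 units in the control libraries and at 718, 736 and 800 after knockdown, and HEY2 rose from 3.33 ± 0.576 to 178 ± 6.22 units (SD, n = 3 each). EFNB2 rose 2.73-fold (log2 1.45, SE 0.05), HEY1 by a log2 change of 1.36, NOTCH1 by 0.60 and DLL4 by 0.50. BMX (-2.39), LTBP4 (-1.41), ALDH1A1 (-1.22) and NOTCH4 (-0.89) fell. SOX17 (-0.13, adjusted p = 0.0156) no longer passed without control replicate 2 (adjusted p = 0.0768) or without knockdown replicate 1 (adjusted p = 0.0739). IGFBP3 (-0.34) no longer passed after quantile normalization. Of 8 venous markers, NR2F2, PLVAP (-2.80), FLT4 (-1.34), GPR126 (-0.59) and EPHB4 (-0.21) fell, and ACKR1 (2.10), EMCN (1.14) and NRP2 (0.84) rose, with the same counts adjusted over the list alone (adjusted p = 0.707).

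Across 12589 genes, 5230 rose and 5239 fell at adjusted p 0.05, which is 83.2% of the genes measured. Of these, 1181 rose and 1818 fell by at least 2-fold, and 1836 and 2437 passed a test against a change of 1.5-fold. The authors' deposited table called 10302 genes, of which 10281 were called here with the same direction. Genes with a high log2 change included NSG1 (5.15), IGDCC4 (4.53), SLC46A3 (3.98), VWCE (3.96), the ceramidase ACER2 (3.92), the antiproliferative gene BTG2 (3.65), CBLN2 (3.65), the hyaluronan receptor LYVE1 (3.59) and MAP1A (3.56). The labels do not say whether the libraries of a hairpin came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The median residual SD was 0.0694 on the log2 scale, against 0.193 in the HUAEC and HUVEC libraries over the 10841 genes in both tables.

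In every list the counts after knockdown were the same adjusted over the list alone. The other list that passed was cholesterol synthesis, in which 17 of 20 genes fell and MVK and LSS rose (camera, adjusted p = 0.00239; adjusted p = 0.879 with an estimated correlation). The sterol oxidase MSMO1 (log2 -2.69), the sterol carrier STARD4 (-1.58) and CYP51A1 (-1.06) fell. Shear-responsive genes did not pass as a list (adjusted p = 0.0503), with 8 of 10 falling, among them the nitric oxide synthase NOS3 (-2.03), KLF4 (-1.30) and KLF2 (-0.70), which were chosen after their values were seen. Markers of smooth muscle were few: ACTA2 (3.48), TAGLN (3.23) and NOTCH3 (1.65) rose and RGS5 (-0.69) fell (adjusted p of the list 0.27). Of the 4 fibroblast markers COL1A2 (0.95) and POSTN (2.39) rose and COL3A1 (-0.55) and FBLN1 (-1.97) fell (0.945). The keratins KRT7 (-2.30), KRT18 (-1.11) and KRT8 (-0.82) fell and KRT19 (0.23) rose (0.27).

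Most other lists held genes of both directions and did not pass the list test. Notch pathway genes rose in 17 of 28 and fell in 8 (adjusted p = 0.27), pan-endothelial markers rose in 10 of 18 and fell in 5 (0.372), and interferon genes rose in 10 of 19 and fell in 5 (0.361). BMP and TGF-beta genes rose in 12 of 23 and fell in 9 (0.709), with ACVRL1 (log2 0.97) and TGFBR2 (1.20) rising and the BMP antagonist NOG (-5.65) and BMP2 (-1.04) falling. Inflammatory genes rose in 9 of 17 and fell in 5 (0.607), where CXCL2 (2.44) and LIF (2.48) rose while CXCL8 (-3.51) and SELE (-2.43) fell. HOX genes rose in 10 of 21 and fell in 10 (0.707), and all 7 HOXB genes were among those that rose, from HOXB2 (0.42) to HOXB8 (2.78), while HOXA11 fell by 0.14 but changed sign and did not pass after quantile normalization (log2 0.0047, adjusted p = 0.946). Axon guidance genes rose in 10 of 23 and fell in 9 (0.707), chemokine genes in 4 and 5 of 9 (0.707) and hypoxia and glycolysis genes in 9 and 8 of 18 (0.918). Of 5 lymphatic markers LYVE1 rose and SOX18 (-1.40) and FLT4 fell (0.72). Examples in these lists were chosen after their values were seen.

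**Figure D2:**
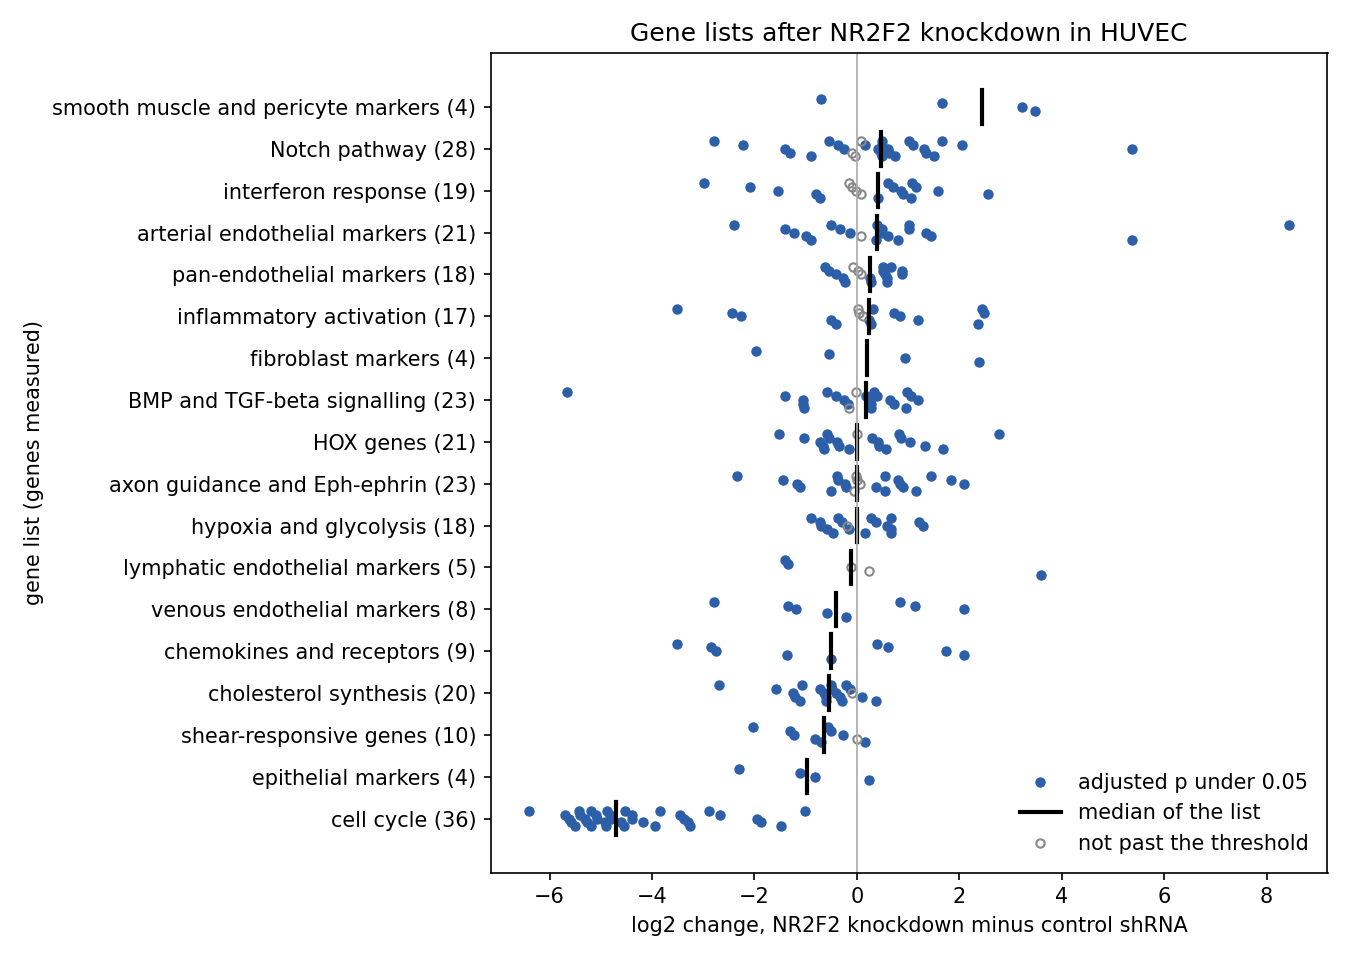
Log2 change after NR2F2 knockdown of each measured gene in 18 lists, with filled points for genes past adjusted p 0.05, open points for the others and a black line at each list's median. All 36 cell cycle genes lie below 0 with a median of -4.71, and the arterial and venous lists hold points on both sides of 0.

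Genes that differed between artery and vein were then followed into the knockdown, with no library shared between the comparisons. Fibroblast and smooth muscle markers were not taken out of the genes higher in HUAEC. COL1A2 and NOTCH3, which rose, and FBLN1, which fell, were among them. Whether such cells were present in the HUAEC or HUVEC cultures, and what they would add to these results, was not tested. Of the genes called in both, 245 of those higher in HUAEC rose after NR2F2 knockdown and 166 fell, whereas of those higher in HUVEC 113 rose and 208 fell. The odds ratio of opposite directions was 2.71 (95% interval 1.99 to 3.72, Fisher's exact test, p = 4.92e-11), with genes as the units, which are not independent replicates. Among the genes with at least a 2-fold difference in both, 60 of those higher in HUAEC rose and 57 fell, and of those higher in HUVEC 20 rose and 62 fell (odds ratio 3.24, interval 1.69 to 6.42). Without HUVEC replicate 3 the genes called in both fell from 732 to 362 (odds ratio 2.28) and without HUAEC replicate 2 to 487 (2.40), and the odds ratio was 2.28 to 3.79 over all 12 libraries left out in turn. EFNB2, HEY2 and GJA5 were among the HUAEC genes that rose and FLT4 and EPHB4 among the HUVEC genes that fell, while NOTCH4 and BMX fell and EMCN and NRP2 rose. The median log2 change was -0.31 for the 368 genes higher in HUVEC and 0.21 for the 475 genes higher in HUAEC, against -0.01 for genes not called. Each set passed the set test (camera, adjusted p = 0.00785 and 0.0312 over 2 tests) but neither did with an estimated correlation (p = 0.123 and p = 0.225 with an estimated correlation). The HUAEC set also did not pass camera without HUAEC replicate 4 (adjusted p = 0.064), without HUVEC replicate 2 (adjusted p = 0.0637) or without HUVEC replicate 3 (adjusted p = 0.098). Nor did it when restricted to genes with a 2-fold difference (adjusted p = 0.113) or with sets from the replicate block by title number (adjusted p = 0.17). Its median was 0.36 without HUVEC replicate 1. Across the 10841 genes in both tables the changes were weakly opposed (Spearman's rho -0.188, Pearson's r -0.146, described only).

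Regions found in all 4 libraries outnumbered regions restricted to a cell type for both H3K27ac and EP300. The H3K27ac lists held 86091 to 103904 peaks and merged into 125347 regions, of which 43762 (34.9%) had a peak in all 4 libraries, 4726 in both HUAEC libraries and neither HUVEC library, and 4805 in both HUVEC libraries and neither HUAEC library. The other 72054 (57.5%) had peaks in another combination of libraries. EP300, a histone acetyltransferase found at enhancers, gave 61085 to 71277 peaks and 80714 regions, with 36938 shared (45.8%), 2971 HUAEC-only, 5903 HUVEC-only and 34902 (43.2%) in another combination. Between replicates of a cell type 80.7% to 85.4% of EP300 peaks overlapped, and between cell types 70.1% to 82%. For H3K27ac these ranges were 67.1% to 85.5% and 68% to 79.3%. HUAEC lists were little or no closer to each other than to HUVEC lists. HUAEC EP300 replicate 2 overlapped HUAEC replicate 1 at 80.7% and the HUVEC lists at 82% and 81%. For HUAEC EP300 replicate 1 the values were 83.4% against 81.6% and 81.3%. For H3K27ac, HUAEC replicate 2 had 67.1% against 68.3% and 72.8%, and HUAEC replicate 1 had 73.5% against 69.5% and 70.8%. Restricted regions were narrower than shared ones, with median widths of 867 bp (HUAEC-only), 1050 bp (HUVEC-only) and 2239 bp (shared) for EP300. Counts of restricted regions depended on requiring both replicates: when a single library stood for its cell type, HUAEC-only EP300 regions numbered 4420 to 8859 and HUVEC-only regions 7807 to 15906. HUAEC-only EP300 regions numbered 8675 and 8859 without HUAEC replicate 1 and 2 and 4859 without HUVEC replicate 1, and HUVEC-only regions numbered 12351 and 15906 without HUVEC replicate 1 and 2. HUAEC-only H3K27ac regions numbered 23488 and 24095 without HUAEC replicate 1 and 2 and 7453 without HUVEC replicate 2. HUVEC-only H3K27ac regions numbered 7883 and 12807 without HUAEC replicate 1 and 2, and 15202 and 11234 without HUVEC replicate 1 and 2.

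Restricted EP300 regions that overlapped restricted H3K27ac mostly did so in the same cell type, but these were a minority, 20.7% of HUVEC-only and 23.9% of HUAEC-only EP300 regions. Of HUVEC-only EP300 regions, 1222 overlapped HUVEC-only H3K27ac and 11 overlapped HUAEC-only H3K27ac, and of HUAEC-only EP300 regions 10 and 710 did (odds ratio 7887, 95% interval 3333 to 18660, Fisher's exact test, p below 1e-300). Leaving out any of the 8 libraries in turn gave odds ratios of 577 (without HUAEC H3K27ac replicate 2) to 1788 (without HUAEC EP300 replicate 1), and the higher-scoring part of each list gave 103820 (interval 5346 to 2016000). Among shared EP300 regions, 92.9% carried H3K27ac in both cell types. Of HUAEC-only regions 24.8% did, and of HUVEC-only regions 41.3%. The HUAEC-only regions with the highest authors' score lay in hg19 at chromosome 1, 2985992 to 2990991, chromosome 10, 101282276 to 101297668, and chromosome 6, 126062885 to 126073602. No NR2F2, ERG or HDAC1 peak of both libraries lay in them, and those on chromosomes 1 and 6 carried H3K27ac in both cell types. The HUVEC-only regions named by the same rule were at chromosome 1, 175473513 to 175486711 and 175504598 to 175507576, and at chromosome 12, 43351126 to 43357726. All 3 carried NR2F2 and HDAC1 peaks, and the chromosome 1 pair carried ERG as well. Scores were tied at the top for 3 HUAEC-only and 8 HUVEC-only regions, with ties broken by position. No gene annotation of hg19 was used here, so regions are given without genes.

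Each protein mapped in HUVEC was found more often at HUVEC-only than at HUAEC-only EP300 regions. Peaks of each NR2F2 library lay at 458 of 5903 HUVEC-only regions (7.76%) and at 41 of 2971 HUAEC-only regions (1.38%). The odds ratio was 6.01 (95% interval 4.35 to 8.30, Fisher's exact test, p = 1.57e-42, adjusted p = 2.24e-42 over 10 region tests). The peaks of the libraries need not overlap each other within a region. ERG, an ETS factor of all endothelium, was at 7.71% and 2.05% (odds ratio 3.98, interval 3.04 to 5.22, adjusted p = 5.14e-31). HDAC1 was at 4.03% and 0.976% (odds ratio 4.26, interval 2.89 to 6.28, adjusted p = 5.71e-18). At shared EP300 regions the proteins were found at 9.28% (NR2F2), 16.5% (ERG) and 25.3% (HDAC1). Regions, not libraries, were the units of these tests. Without HUVEC EP300 replicate 1 the odds ratios were 2.92 for NR2F2, 1.301 for ERG and 1.72 for HDAC1, and without replicate 2 they were 4.04, 1.87 and 1.93. Without HUAEC EP300 replicate 1 they were 8.79, 6.63 and 6.87, and without HUAEC replicate 2 they were 10.3, 8.56 and 6.55. With the higher-scoring part of each list alone, the odds ratio of NR2F2 was 3.57.

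**Figure D3:**
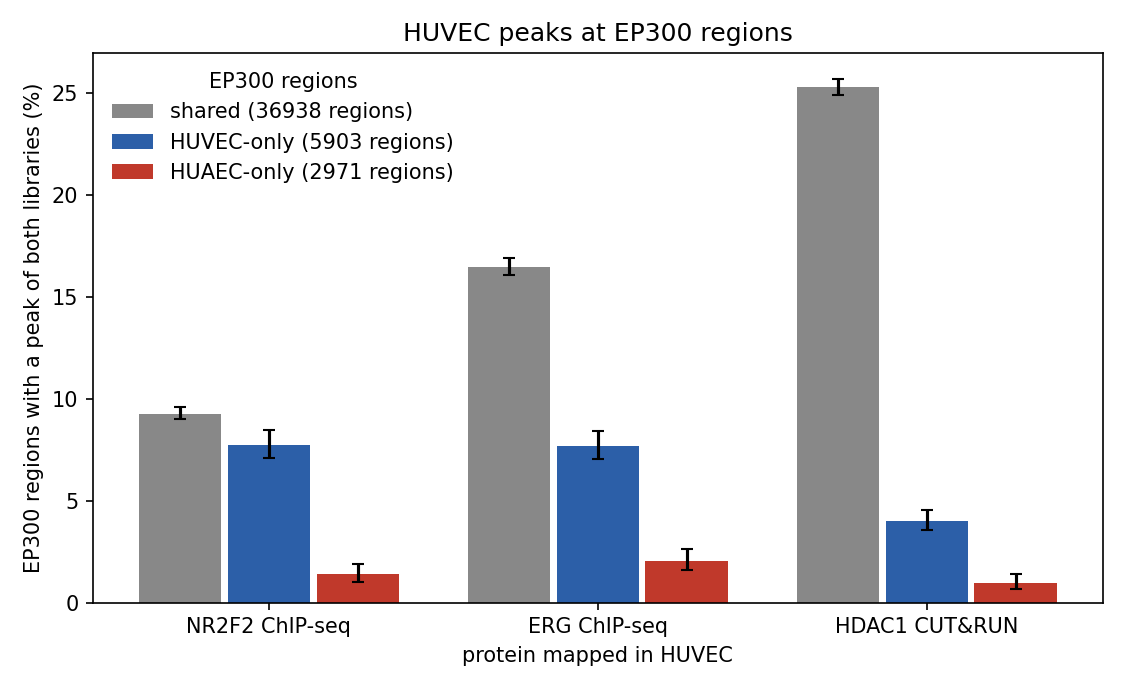
Percent of shared (grey), HUVEC-only (blue) and HUAEC-only (red) EP300 regions that overlap a peak of each HUVEC library of NR2F2, ERG or HDAC1. Whiskers are Wilson 95% intervals over regions. NR2F2 is at 7.76% of HUVEC-only and 1.38% of HUAEC-only regions, and HDAC1 is at 25.3% of shared regions.

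HDAC1 and ERG were each found more often at EP300 regions with an NR2F2 peak than at those without. Of 5022 NR2F2 peak regions present in both libraries, 92.3% lay at an EP300 region, 90.4% at H3K27ac of both HUVEC libraries, 52.4% also at ERG and 31.5% also at HDAC1. Over shared and HUVEC-only EP300 regions, HDAC1 was at 44.6% of those with NR2F2 and at 20.2% of those without (odds ratio 3.19, 95% interval 2.98 to 3.41, Fisher's exact test, p = 1.48e-230). ERG was at 59.9% and 10.8% (odds ratio 12.3, interval 11.4 to 13.2, p below 1e-300). At HUVEC-only regions alone, a test added after the data were seen, HDAC1 was at 14.6% of those with NR2F2 and 3.14% of those without (odds ratio 5.29, interval 3.91 to 7.14, Fisher's exact test, p = 4.25e-22), and ERG at 41.5% and 4.87% (odds ratio 13.9). There the odds ratio of HDAC1 was 8.06 without HUVEC EP300 replicate 2 and 9.31 with an overlap of at least 0.5 of the shorter interval, and that of ERG was 22.96 without HUVEC EP300 replicate 1 and 9.05 with the higher-scoring part of each list. All 3 proteins were at 1182 of the 3429 shared EP300 regions with NR2F2 and at 37 of the 458 HUVEC-only ones. Pooled over 25 strata of region width and score rank, an alternative chosen after the data were seen, the odds ratio of HDAC1 at NR2F2 regions was 2.05 (interval 1.90 to 2.21). That of ERG was 8.21 (interval 7.604 to 8.865). At HUVEC-only regions alone the pooled odds ratios were 4.40 for HDAC1 and 9.67 for ERG. The ERG lists were of unequal length, with 38420 and 8890 peaks: 98.8% of the shorter list overlapped the longer and 22.7% of the longer overlapped the shorter.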

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

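The scalings, the strata, 2 gene lists, the 4 tests within shared or HUVEC-only regions alone with their alternatives, and the alternatives of the ratios of odds ratios were chosen only after the data were seen, and all other alternatives before. Read depth is unknown for every library, so what it limits could not be measured, and groups of 2 or 3 libraries limit the precision. The planned count-model alternatives, gene links and distance filters were not run, because the values are not whole-number counts and no hg19 annotation was used. Having no filter on low values is the setting reported. The causes of the changes below were not tested, except where fewer libraries or a stricter threshold are the change itself.

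Whether the same replicate number marked paired HUVEC and HUAEC libraries was left open. Correlations of the deviations from group means were 0.044 and -0.104 for the same title number. For the same library name number they were -0.095 and 0.071. Pairs with different title numbers went from -0.109 to 0.168. With 2 same-number pairs per numbering, these values cannot exclude a pairing by cord. In the knockdown table the same title number gave -0.224, 0.021 and -0.098. A replicate block by title number gave 168 genes higher in HUVEC and 262 higher in HUAEC, 382 of all 430 being among the 900. With it BMX did not pass (adjusted p = 0.0965) and IGFBP3 did (adjusted p = 0.00131). A replicate block by library name number gave 511 and 822 and turned GJA4 to -1.11. The latter block also took 5 other named genes past the threshold, among them CXCR4 (-2.04), IGFBP3 (-4.54) and ALDH1A1 (0.66). Each of these blocks has only 2 pairs, and libraries without a partner add nothing to the estimated change. The counts gained or lost with a block therefore do not show whether libraries were paired. After knockdown a replicate block gave 5115 rising and 5135 falling. At adjusted p under 0.01 the artery and vein counts were 148 and 226, and against a change of 1.5-fold they were 80 and 152 (1836 and 2437 after knockdown). Leaving out each library gave 186 to 335 genes higher in HUVEC, 272 to 516 higher in HUAEC, 5001 to 5208 rising and 5035 to 5190 falling. With an estimated correlation, 0 of 8 lists passed between the cell types and 1 of 2 after knockdown, and fry, which does not compare a list with other genes, passed 5 and 15. Leaving out each library gave 7 to 9 lists between the cell types and 2 to 3 after knockdown. The replicate block by title number gave 9 and 3. Quantile normalization moved the median of all genes after knockdown by 0.09, turned 60 called genes and gave 5872 rising and 4684 falling, while scaling to equal totals gave 4700 and 5698.

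The median after knockdown of genes higher in HUVEC, -0.31, lost its call with an estimated correlation (p = 0.123). That of genes higher in HUAEC, 0.21, did so too (adjusted p = 0.225), as it did for 2-fold sets (0.21, adjusted p = 0.113) and with sets from the replicate block by title number (0.19, adjusted p = 0.17). Leaving out each library gave -0.43 to -0.25 and 0.19 to 0.36, and fry passed both.

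With the higher-scoring part of each list alone, H3K27ac had 29034 shared, 2534 HUAEC-only and 2008 HUVEC-only regions, and EP300 23221, 1784 and 2753. Leaving out each library gave 6498 to 24095 HUAEC-only and 7883 to 15202 HUVEC-only H3K27ac regions, and 4420 to 8859 and 7807 to 15906 EP300 regions. The odds ratios of the 10 region tests kept their direction under the alternatives run for each, with p under the threshold where one was computed and, for the strata, intervals above 1. They went from 2.92 to 10.3 for NR2F2, 1.301 to 8.56 for ERG and 1.72 to 6.87 for HDAC1 without each library, and at NR2F2 peaks of HUVEC-only regions from 3.93 to 8.06 for HDAC1 and 10.2 to 22.96 for ERG. Of the values of named genes under alternatives, 1218 kept their side of the threshold, 22 fell below it, 10 rose past it and 1 turned. A change of direction counted as turned only where the value passed in at least 1 of the settings. The 1218 can therefore include changes of direction where neither value passed.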

Other observations

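The lists of p53 target genes and lysosomal genes, the check of the spread between libraries, the comparison of NR2F2 with HDAC1 and the alternatives of its ratios to ERG and HDAC1 were chosen only after the result was seen. After NR2F2 knockdown, 29 of 30 p53 target genes rose, 21 of them by at least 2-fold, with a median log2 change of 1.504 (camera, adjusted p = 2.74e-12; adjusted p = 0.00258 with an estimated correlation). Some members had been seen to rise before the list was written, so its test is not independent evidence. The cell cycle inhibitor CDKN1A rose 5.94-fold, from 16945 ± 473 to 100700 ± 2205 units (SD, n = 3 each), the stress cytokine GDF15 rose 7.42-fold, SESN2 7.54-fold and BTG2 12.5-fold. The proapoptotic BBC3 rose 5.14-fold and the p53 ligase MDM2 2.48-fold. PHLDA3 did not pass (adjusted p = 0.326).

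All 32 lysosomal genes rose after knockdown, 17 by at least 2-fold, with a median log2 change of 1.15 (adjusted p = 2.66e-11; adjusted p = 0.0384 with an estimated correlation). This list too was written after knockdown values had been seen, so its test is not independent evidence. The protease CTSD rose 4.27-fold, CTSA 3.74-fold, the saposin precursor PSAP 3.17-fold, from 58866 ± 1916 to 186560 ± 5728 units (SD, n = 3 each), and the lysosomal membrane protein LAMP1 2.19-fold. Between HUVEC and HUAEC the same lists moved little: 1 of 28 p53 targets was higher in HUVEC and 1 in HUAEC, and 3 of 32 lysosomal genes were higher in HUAEC. The list test gave adjusted p = 0.00318 for each there, and adjusted p = 0.381 with an estimated correlation.

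After NR2F2 knockdown 10469 of 12589 genes passed the threshold, against 900 of 10924 between HUVEC and HUAEC. The scaling of the libraries does not account for it, since 10398 genes still passed under the scaling that left fewest. Libraries of one group lay closer together in the knockdown table, with a residual SD 0.359 times that of the other table, so part of the count may come from this closeness, which technical replicates would also give. Whether loss of NR2F2, of cell division or another effect of a single hairpin moved these genes stays open, as only 1 hairpin was compared with 1 control. The 10 splits of 6 libraries into groups of 3 are too few for a share under 0.05: only 1 split, the real one, gave 10469 genes and the highest of the others 0, and for HUVEC against HUAEC only 1 split, the real one, gave 900 and the highest of the others 1.

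Genes higher in HUAEC rose, and genes higher in HUVEC fell, more often than the reverse after knockdown (odds ratio 2.71). At 2-fold in both comparisons, 60 of the HUAEC genes rose and 57 fell, and 20 of the HUVEC genes rose and 62 fell. Of all genes in the knockdown table, 1181 rose and 1818 fell by at least 2-fold. The odds ratio was not lowered by pooling over 10 strata of expression (3.1, lower bound 2.26). Nor was it lowered by quantile normalization of both tables (2.95) or scaling to equal totals (2.875, lower bound 2.08). These bounds take genes as independent, which they are not. They therefore do not exclude a trend with expression level or the scaling of the libraries as a part of the cause. Leaving out the cell cycle, cholesterol and interferon lists kept 729 of the 732 genes (lower bound 1.958), too small a change to test a wider effect of cell division, which stays open. That NR2F2 holds part of the venous RNA pattern in HUVEC is a hypothesis that 1 hairpin against 1 control does not decide. Neither set passed camera with an estimated correlation, although the medians of -0.31 and 0.21 are the same there. NOTCH4 and BMX went the other way, and the fall of cell cycle genes was not separated from NR2F2 itself.

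NR2F2 peaks favoured HUVEC-only over HUAEC-only EP300 regions (odds ratio 6.01). The odds ratio pooled over 25 strata of width and score rank had a lower bound of 3.67. Greater width of HUVEC-only regions, or a higher rank within their own cell type's lists, is therefore not the whole cause. A higher score as such was not tested, since ranks within a cell type remove differences between cell types. Median peak scores were 260.8 and 297.1 in the HUVEC EP300 lists and 191 and 217.5 in the HUAEC EP300 lists. Any protein mapped in HUVEC may favour regions active in HUVEC, as ERG (3.98) and HDAC1 (4.26) did as well. The odds ratio of NR2F2 was 1.503 times that of ERG, with a lower bound of 1.11, and the interval lay above 1 under 10 of 12 alternatives but not without HUAEC EP300 replicate 2 (1.20, interval 0.937 to 1.59) or with the higher-scoring part of each list (1.33, interval 0.97 to 1.81). Set against HDAC1 the ratio was 1.42 (interval 0.84 to 2.31) and went from 0.906 to 2.09 over 12 alternatives, with 6 intervals above 1, among them those without HUVEC EP300 replicate 1 (1.69) or 2 (2.09), so a preference of NR2F2 beyond that of HUVEC-mapped proteins in general stays open.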
